A study of Arabidopsis thaliana with 27 samples.

How the data were processed

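Seedlings of the wild type Col-0 and of the lines labelled hex and GNLox were grown for 7 days in constant light of 60 µmol m-2 s-1 at 22 °C. They were harvested before treatment (t0), after 6 h of high light at 1200 µmol m-2 s-1 (HL) or after 6 h of mock treatment at 60 to 70 µmol m-2 s-1 (LL), both at 20 to 22 °C. The label of the mock group names low light while the protocol text uses another abbreviation for it, and both were read as the same 6 h mock treatment. Each group has 3 libraries, each of 30 seedlings, made with a stranded mRNA kit with 11 cycles and read as single reads of 100 nt. Light level, mock treatment and growth come from the labels, and whole seedlings were measured, so no organ is separated.

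Per the file headers, the deposited tables hold read counts per gene for 1 library each (exon, gene, intron and exon-exon reads, in total and unique forms). They also hold RPKM that the authors computed from total exon reads, exon length and a number of mapped reads larger than the sum over the listed genes. The TPM values are deposited as RPKM rescaled to a sum of 1000000 per library. The genome build is TAIR10 by the submitters' processing notes, and the aligner and counting tool are not given in the sources used here. Of 27655 gene identifiers 27445 are in the reference annotation used here for coordinates (TAIR10.1), 27444 of them with the same start and end. RPKM and TPM were used only for a check of the units, and intron and exon-exon reads were not analysed here.

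Total exon reads are the measure throughout, a choice made after the columns were seen, and reads unique to a gene and total gene reads are alternatives. The libraries hold 28902849 to 42291249 exon reads, and 1.808 to 2.315% of the reads match more than 1 gene. A count of 3 corresponds to 0.0709 to 0.1038 CPM. Between replicates the chi-square per degree of freedom is 2.8 to 47.68, so the spread exceeds counting noise. Genes with enough reads in the 9 groups (filterByExpr) were kept, 21690 in all. Counts were scaled by TMM and all 27 libraries were fitted in 1 model with 1 coefficient per group (edgeR 4.0.16, glmQLFit and glmQLFTest, R 4.3.3). All adjusted p values are Benjamini-Hochberg values within 1 of 14 comparisons, with 0.05 as threshold. A difference of high-light responses is the contrast of the 4 group coefficients. A standard error was taken as the log2 fold change over the square root of the F value, and ± beside CPM is the SD of 3 libraries.

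Gene lists (28 pathway lists and 6 marker lists, 467 genes) and the rule for naming genes were fixed before the data were examined. The rule names the 6 B-GATA genes, the genes with the highest and lowest fold changes (8 each way for high against low light, 5 each way otherwise, mean log2 CPM of at least 3, nuclear, with no overlap between the groups compared), and up to 4 members of a described list with the smallest adjusted p. Lists with at least 4 measured genes (32) were tested by camera with a preset correlation of 0.01 between genes, and by camera with an estimated correlation and by fry (limma 3.58.1). For each list the members called among all genes are given, and those called when adjusted over the list alone.

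A fold against a group with 0 counts uses a floor of 3 counts over the group, and for 1 to 3 counts the ratio has a 95% counting interval. The effects of hex and GNLox were compared by correlation across genes and by overlap of calls, beside 20 simulations in which both share the Col-0 libraries and nothing else. The analysis was tested on data with simulated changes. For high against low light in Col-0 73.1% of 1.5-fold, 79.1% of 2-fold and 97% of 4-fold changes were recovered with 2.9% false calls, and for the hex difference of responses 43.3, 65.7 and 95.5% with 4.2% false calls. By DESeq2 1.42.0 8.2 to 9.5% of calls were false, and of 20 random gene sets 0 passed by camera.

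The alternatives chosen in advance were the DESeq2 Wald test, DESeq2 size factors, no filter or at least 50 counts in 3 libraries, only the compared libraries, the replicate number as a block, a 2-fold threshold, unique reads, organelle genes left out, and each library left out in turn. Total gene reads, 2 libraries left out together, the rank correlation and further alternatives for the correlations were added after the data were seen. Plastid and mitochondrial genes were not compared because the libraries were made from polyadenylated RNA. Whether the counting used strand is not given in the sources used here, so genes that share reads or lie within others are given as uncertain. Other named genes overlap a neighbour with at least 0.1 of their reads by 163 bp or less and have at least 90% unique reads.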

Results

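RNA from 7-day-old Arabidopsis seedlings was compared in 9 groups of 3 libraries each: the wild type Col-0, the line labelled hex and the line labelled GNLox, each before treatment (t0), after 6 h of low light (LL) and after 6 h of high light (HL). By the labels, hex carries mutations in 6 B-class GATA factors of the LLM-domain type (GNC, GNL, GATA15, GATA16, GATA17 and GATA17L), and GNLox overexpresses GNL. The libraries hold 28902849 to 42291249 exon reads, and 21690 of 27655 listed genes had enough reads to be tested. The biological coefficient of variation over all genes is 9.9%. The first principal component of the 27 libraries holds 46.7% of the variance and the second 31.4%. Plastid genes take 0.0197 to 0.141% of the exon reads, so single plastid genes are not described here.

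**Figure D1:**
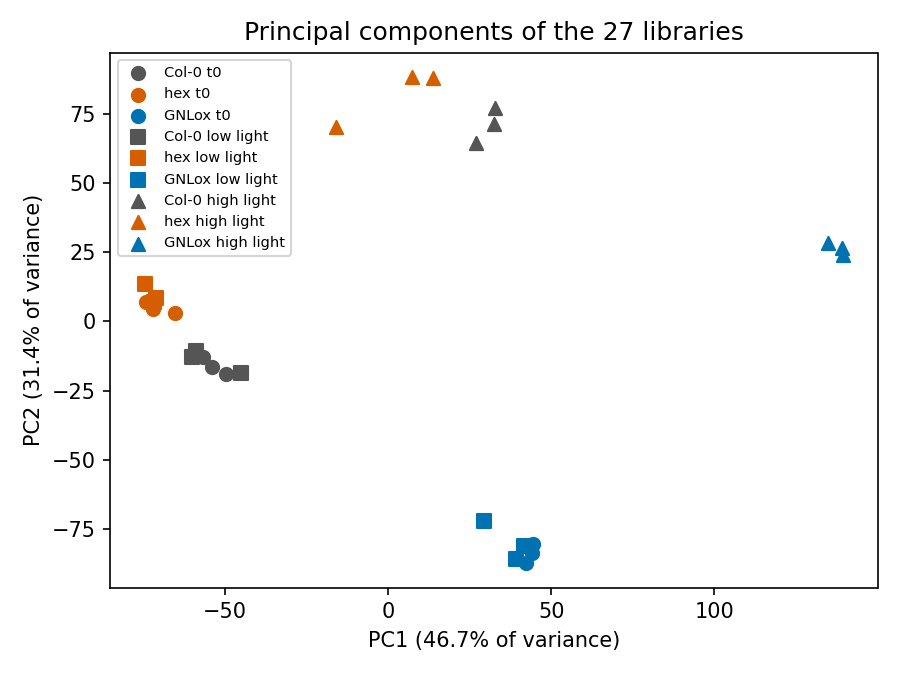
First 2 principal components of the log2 CPM of the 27 libraries. Each point is 1 library, and colour and shape give genotype and treatment.

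GNL, which codes for a GATA factor active in greening, is read at 2620 ± 180 CPM (counts per 1000000, mean ± SD, n = 3) in GNLox at t0 and at 19.2 ± 3.3 CPM in Col-0. The excess in GNLox over Col-0 is 136-fold at t0 (adjusted p = 1.09e-17), 185-fold in low light (adjusted p = 4.93e-18) and 123-fold in high light (adjusted p = 2.77e-17), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the libraries labelled hex, all 6 B-GATA genes are read at t0. GATA16, a small B-GATA factor, is 4.07-fold higher there than in Col-0 (14.8 ± 0.94 against 3.61 ± 0.63 CPM, adjusted p = 4.44e-09), and GATA15 is 2.11-fold higher (26.4 ± 2.5 against 12.5 ± 0.81 CPM, adjusted p = 1.75e-05). GATA17L fell in hex (log2 fold change -0.73, adjusted p = 3.86e-05) and so did GNC (log2 fold change -0.78, adjusted p = 0.0118, and 0.0604 without hex t0 replicate 3). GNL (18.5 ± 2.7 CPM, adjusted p = 0.819) and GATA17 (10.4 ± 0.71 CPM, adjusted p = 0.985) passed no threshold in hex at t0. Reads summed over a gene cannot show whether a transcript is truncated or carries an insertion. In GNLox the other 5 genes are read below Col-0 at t0: GNC at 3.44 ± 1.5 against 34.2 ± 1.7 CPM, GATA15 at 4.75 ± 0.78 against 12.5 ± 0.81, GATA16 at 0.328 ± 0.18 against 3.61 ± 0.63, GATA17 at 5.26 ± 0.98 against 10.4 ± 1.6 and GATA17L at 16.9 ± 1.5 against 26.6 ± 2.3. In Col-0, high light raised GNL 2.03-fold over low light (27.9 ± 5 against 13.7 ± 3.5 CPM, adjusted p = 5.54e-06) and GATA16 1.76-fold (adjusted p = 0.00018), and GATA15 fell (log2 fold change -0.70, adjusted p = 0.00101).

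**Figure D2:**
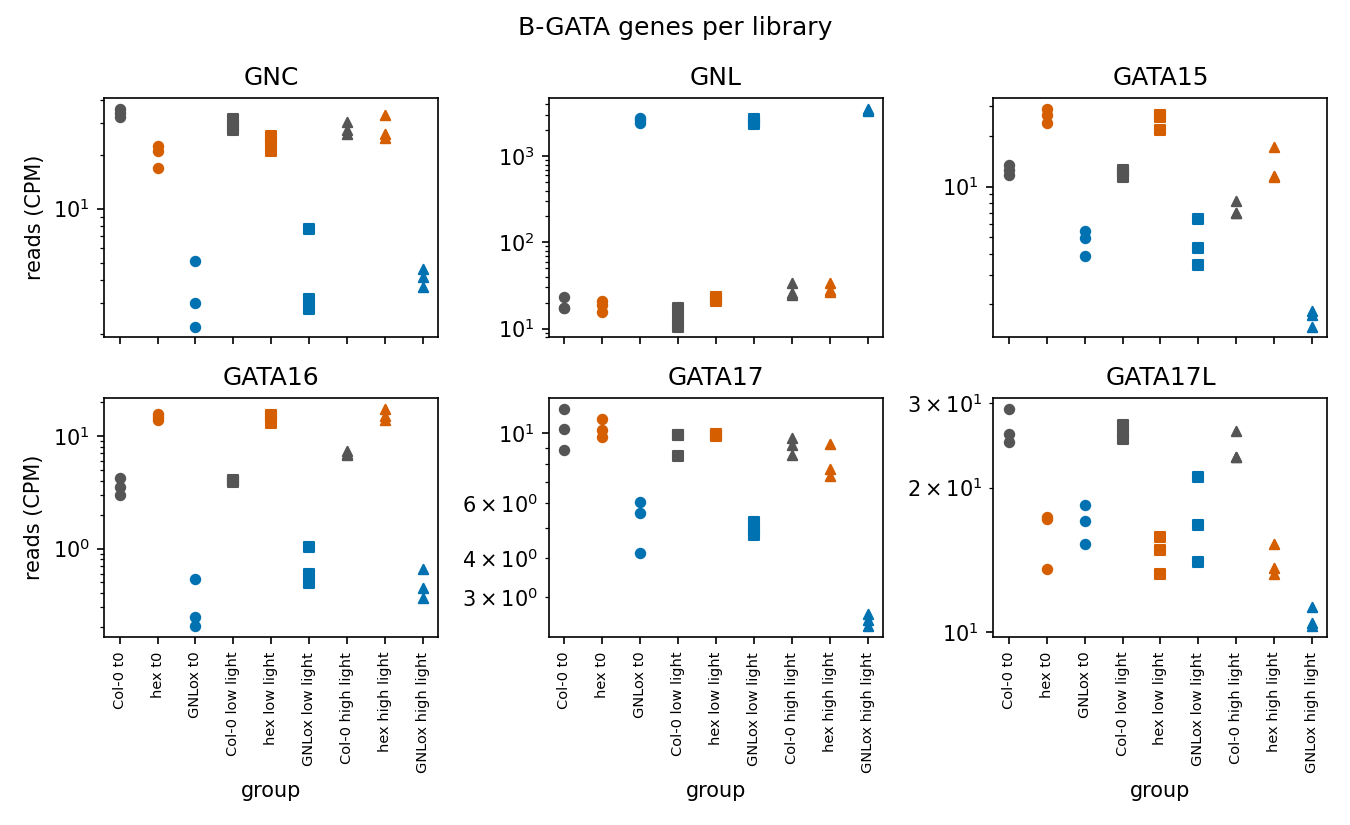
Reads of the 6 B-GATA genes in each of the 9 groups, as CPM on a log scale. Points are libraries, with 3 in each group.

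LTP4, a gene for a lipid-transfer protein, is read in Col-0 at 189 ± 26 CPM in high light and at 0 counts in the 3 low-light libraries, at least 6510-fold higher with a floor of 3 counts over the group. ELIP1, which codes for an early light-induced protein of the thylakoid, rose 46-fold (2420 ± 210 against 52.5 ± 9.2 CPM, n = 3 and 3). CHS, the gene for the entry enzyme of flavonoid synthesis, rose 4.61-fold (2470 ± 90 against 536 ± 29 CPM). LHCB1.4, which codes for an antenna protein of photosystem II, fell 60.3-fold (34.2 ± 14 against 2070 ± 370 CPM).

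The test calls 13173 genes between high and low light in Col-0 at an adjusted p under 0.05, 6667 higher and 6506 lower in high light, and 3409 of them changed at least 2-fold. After LTP4 (adjusted p = 7.9e-16), the genes with the highest fold changes are HSP17.6II (log2 fold change 9.92 ± 1.217, mean ± standard error, 60.5 ± 29 against 0.0597 ± 0.06 CPM, adjusted p = 3.17e-07), CAD8 (9.88 ± 1.244, adjusted p = 4.65e-07), AT1G71000 (9.54 ± 0.88, adjusted p = 4.36e-09) and AT5G05220, which has 1451 counts in high light and 3 in low light, a ratio of 483 with a counting interval of 165 to 2350. DIR1_2 has the lowest fold change, at least 472-fold lower with 0 counts in high light, but its count is uncertain because the gene lies within AT5G48480 on the opposite strand and none of its reads is unique to it. LHCB1.4 (log2 fold change -5.91 ± 0.306, adjusted p = 4.21e-13) comes next, then AT3G12900 (-5.56 ± 0.518, adjusted p = 5.09e-09), AT1G15125 (-5.32 ± 0.275, adjusted p = 4.19e-13) and AT3G04210 (-5.29 ± 0.32, adjusted p = 4.76e-12). AT1G15125 overlaps AT1G15120 over 183 bp on the same strand, so its count is uncertain too.

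Of the 32 gene lists tested together by camera, 17 pass an adjusted p under 0.05 in Col-0, 12 towards higher and 5 towards lower values. With the correlation between genes estimated from these libraries 7 pass, and by fry 21 pass. All 15 ABA and dehydration genes rose (15 when adjusted over the list alone, median log2 fold change 2.58, adjusted p = 2.05e-15), with P5CS1 10.4-fold (adjusted p = 4.3e-16) and HAI1 81.9-fold (adjusted p = 3.14e-13). Of 12 phenylpropanoid and flavonol genes 10 rose (10 alone, median 1.93, adjusted p = 6.19e-19), among them F3H 5.8-fold (adjusted p = 6.42e-16) and CHI 3.84-fold (adjusted p = 7.08e-15). All 7 anthocyanin genes rose (7 alone, median 3.03), with a list value of adjusted p = 5.07e-06, and adjusted p = 0.194 with an estimated correlation. SAT, which codes for a sinapoyltransferase of anthocyanins, rose 6.44-fold (adjusted p = 1.71e-13). Of 11 flavonoid regulators 8 rose and 2 fell (8 and 2 alone, median 2.15, adjusted p = 0.00049), led by MYB90 at 43.2-fold (adjusted p = 1.59e-12) and MYB75 at 29.1-fold (adjusted p = 6.31e-12). In the ELIP and photoprotection list 9 of 11 rose (9 alone, median 0.53, adjusted p = 1.19e-08), with ELIP2 31.7-fold (adjusted p = 1.35e-14) and PSBS 2.18-fold (adjusted p = 2.03e-11). CBF and COR genes (7 of 9 rose, 7 alone, median 2.36, adjusted p = 1.4e-09) include COR15A at 66.1-fold (adjusted p = 2.1e-15).

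Heat shock genes rose in Col-0 for 25 of 27 members (26 alone, median 3.62, adjusted p = 3.92e-09, and adjusted p = 0.274 with an estimated correlation), among them HSP70-4 17-fold (adjusted p = 8.23e-09). Antioxidant enzymes rose for 20 and fell for 2 of 27 (20 and 2 alone, median 0.64, adjusted p = 6.29e-07). ROS signalling genes rose for 10 and fell for 2 of 15 (10 and 2 alone, median 1.81, adjusted p = 0.0128, and adjusted p = 0.567 with an estimated correlation). Tocopherol genes rose for 5 of 6 (5 alone, median 0.98, adjusted p = 0.001). Carotenoid genes rose for 10 and fell for 1 of 13 (10 and 1 alone, median 0.58, adjusted p = 0.00061, and adjusted p = 0.244 with an estimated correlation). Jasmonate genes rose for 11 of 17 (11 alone, median 1.11, adjusted p = 0.02, and adjusted p = 0.641 with an estimated correlation).

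The light-harvesting antenna fell in Col-0 for 17 of 21 genes (17 alone, median -1.48, adjusted p = 1.33e-13, and adjusted p = 0.104 with an estimated correlation). LHCB4.2 fell 5.12-fold (adjusted p = 1.16e-13) and LHCB2.3 fell 12-fold (adjusted p = 3.65e-13), and LHCB7 rose 3.57-fold (adjusted p = 7.88e-15). Photosystem and Rubisco subunits fell for 26 and rose for 1 of 31 (26 and 1 alone, median -0.68, adjusted p = 1.15e-09, and adjusted p = 0.311 with an estimated correlation). Nitrate assimilation fell for 10 and rose for 1 of 15 (10 and 1 alone, median -0.60, adjusted p = 0.0123, and adjusted p = 0.314 with an estimated correlation). Auxin response genes fell for 8 of 10 (8 alone, median -0.86, adjusted p = 0.00221, and adjusted p = 0.156 with an estimated correlation). Root markers fell for 13 and rose for 1 of 16 (13 and 1 alone, median -0.81, adjusted p = 0.00847, and adjusted p = 0.274 with an estimated correlation). IRT1 is 9.03-fold lower (adjusted p = 1.47e-08).

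The other 15 lists tested do not pass in Col-0. Chlorophyll synthesis has 9 genes higher and 5 lower of 24 (9 and 5 alone), a median of 0.08 and a mean of -0.09, so the 2 summaries differ in sign (adjusted p = 0.896). The chloroplast regulators (3 higher and 2 lower of 8, 5 and 2 alone, median 0.15, adjusted p = 0.846) hold SIG5 at 3.73-fold higher (adjusted p = 2.62e-10). Light signalling (10 higher and 8 lower of 18, 10 and 8 alone, median 0.26, adjusted p = 0.758) holds CRY1 at 2.02-fold lower (adjusted p = 3.65e-13) and PHYB at 1.5-fold higher (adjusted p = 1.72e-12). The circadian clock list (9 higher and 6 lower of 16, 9 and 6 alone) has a median of 0.27 and a mean of -0.01. Sugar-starvation genes fell for 6 of 9 (6 alone, median -1.02, adjusted p = 0.084), with DIN10 4.22-fold lower (adjusted p = 1.13e-06). Sugar and starch genes rose for 4 and fell for 1 of 6 (4 and 2 alone, median 1.52, adjusted p = 0.0553), with APL3 4.16-fold higher (adjusted p = 5.62e-11). Salicylate and immunity (6 of 14 lower, 6 alone, median -0.71, adjusted p = 0.257), glucosinolates (5 lower and 1 higher of 20, 5 and 1 alone, median -0.12, adjusted p = 0.284), cytokinin response (6 of 12 lower, 6 alone, median -0.33, adjusted p = 0.153) and cell cycle (10 of 22 lower, 9 alone, median -0.31, adjusted p = 0.187) are below 0 at the median.

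FAMA, a regulator of guard cells, fell in Col-0 1.45-fold (adjusted p = 1.2e-06), and the stomatal lineage has 3 genes lower of 9 (2 alone, median -0.21, adjusted p = 0.733). Xylem genes rose for 2 and fell for 1 of 7 (2 and 1 alone, median 0.07, adjusted p = 0.844). Seed storage has 1 gene higher of 5 (1 alone), EM6 at 4.63-fold (adjusted p = 0.00204), and its median of -0.99 and mean of -0.01 have the opposite sign to its test (adjusted p = 0.846). Gibberellin genes (6 higher and 5 lower of 15, 6 and 5 alone, adjusted p = 0.758) have a median of -0.09 and a mean of -0.03 while the test points upwards, with GASA6 5.25-fold lower (adjusted p = 1.35e-11). The B-GATA list itself (2 higher and 1 lower of 6, 2 and 1 alone) has a median of -0.06 and a mean of 0.15 (adjusted p = 0.758).

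In the libraries labelled hex ELIP1, the early light-induced gene, rose 18.7-fold over low light (2090 ± 180 against 111 ± 21 CPM, n = 3 and 3). P5CS1, which codes for an enzyme of proline synthesis, rose 13.6-fold (451 ± 55 against 33.2 ± 2.3 CPM). LHCB1.4, the antenna gene, fell 26.2-fold (31.1 ± 13 against 817 ± 120 CPM). In hex, high light changed GATA15 (1.85-fold lower, adjusted p = 7.15e-05), GNL (1.33-fold higher, adjusted p = 0.0245) and GATA17 (1.23-fold lower, adjusted p = 0.038). The list has a median of 0.01 and a mean of -0.08 (adjusted p = 0.743, 1 higher and 2 lower of 6, 1 and 2 alone). For GNL the adjusted p is 0.0503 without hex t6LL replicate 1, 0.0851 without hex t6LL replicate 3 and 0.108 without hex t6HL replicate 1. For GATA17 it is 0.0713, 0.0723 and 0.0784 without hex t6LL replicate 1, 2 or 3, 0.12 and 0.17 without hex t6HL replicate 2 or 3, and 0.0616 with only the compared libraries.

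Between high and low light in hex 11069 genes are called, 5718 higher and 5351 lower, with 2534 at 2-fold or more. LTP4 has the highest fold change (log2 11.31 ± 0.358, 135 ± 49 against 0.0493 ± 0.017 CPM, adjusted p = 5.1e-15). AT4G33467 and AT5G05220 follow, with 3 or fewer counts over the 3 low-light libraries and ratios of 815 (counting interval 225 to 6730) and 797 (220 to 6580). The lowest are DIR1_2 (at least 693-fold lower, 0 counts in high light, with the uncertainty given above), PCC1 (35-fold lower, adjusted p = 6.32e-05), AT3G12900 (27.1-fold lower, adjusted p = 3.6e-08) and LHCB1.4 (adjusted p = 1.25e-11). Of the reads of PCC1 69.2% are unique to it, and of those of AT4G33467 68.8%, so both counts are uncertain.

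In hex 18 of the 32 lists pass for high against low light, 13 upwards and 5 downwards, with 7 under an estimated correlation and 24 by fry. ABA and dehydration (15 of 15 higher, 15 alone, median 3.24, adjusted p = 3.48e-25) again holds HAI1, 68.9-fold higher (adjusted p = 9.09e-13). In phenylpropanoid and flavonol 11 of 12 rose (11 alone, median 1.48, adjusted p = 6.02e-22), with F3PH 8.59-fold higher (adjusted p = 1.96e-14). Flavonoid regulators rose for 8 of 11 (8 alone, median 2.13, adjusted p = 1.38e-05), with MYB90 16-fold higher (adjusted p = 1.87e-10). CBF and COR genes rose for 8 of 9 (8 alone, adjusted p = 1.46e-13), with a median of 2.83, or 2.04 when genes at or under the floor take their bound. Heat shock rose for 26 of 27 (26 alone, median 2.93, adjusted p = 7.6e-09, and adjusted p = 0.285 with an estimated correlation). The antenna fell for 17 and rose for 3 of 21 (17 and 3 alone, median -1.20, adjusted p = 4.45e-14, and adjusted p = 0.0962 with an estimated correlation). Cell cycle genes fell for 11 of 22 (12 alone, median -0.37, adjusted p = 0.0145, and adjusted p = 0.648 with an estimated correlation). Light signalling rose for 11 and fell for 5 of 18 (11 and 6 alone, median 0.25, adjusted p = 0.00158, and adjusted p = 0.16 with an estimated correlation). Stomatal lineage genes have a median of -0.16 and a mean of 0.04 (2 higher of 9, 2 alone, adjusted p = 0.962).

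Between Col-0 and hex, the same 4676 genes are higher in high light in both, where 1758 would be shared by chance, and 4579 are lower in both (1605 by chance). In 56 genes the direction is opposite (3360 by chance), and the log2 fold changes correlate at 0.865.

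In GNLox, high light moved most genes of the cold and dehydration lists upwards and most cell cycle and glucosinolate genes downwards. HAI1, which codes for a phosphatase of the abscisic acid pathway, rose 450-fold over low light (234 ± 18 against 0.524 ± 0.18 CPM, n = 3 and 3). KIN1, a dehydration and cold gene, rose 118-fold (62.7 ± 7.9 against 0.542 ± 0.29 CPM). CYP79B3, which codes for an entry enzyme of indole glucosinolates, fell 4.61-fold (13.2 ± 3 against 60.9 ± 4.4 CPM). GATA17 (1.95-fold lower, adjusted p = 1.59e-06), GATA15 (2.78-fold lower, adjusted p = 2.69e-06) and GATA17L (1.62-fold lower, adjusted p = 2.89e-05) fell in GNLox, and GNL rose 1.36-fold (adjusted p = 0.00827).

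Between high and low light in GNLox 14531 genes are called, 6556 higher and 7975 lower, with 4804 at 2-fold or more. AT5G24080 has the highest fold change, with 12787 counts in high light and 3 in low light (ratio 4770, counting interval 1630 to 23100). LTP4 (log2 fold change 11.61 ± 0.331, adjusted p = 3.72e-16), ERF054 (10.39 ± 0.532, adjusted p = 2.4e-13), AT5G05220 (9.98 ± 0.592, adjusted p = 2.29e-12), ERF053 (9.81 ± 0.544, adjusted p = 8.14e-13) and HAI2 (9.51 ± 0.386, adjusted p = 8.05e-15) follow. The lowest are AT3G12900 (-6.80 ± 0.563, 2.01 ± 0.72 against 224 ± 18 CPM, adjusted p = 5.19e-10), AT5G38820 (-6.05 ± 0.395, adjusted p = 1.08e-11), CYP82C4 (-5.88 ± 0.472, adjusted p = 3.13e-10), AT5G46900 (-5.86 ± 0.506, with 80.4% of its reads unique to it), IRT2 (-5.63 ± 0.4, adjusted p = 4.28e-11) and FRO2 (-5.51 ± 0.363, adjusted p = 1.29e-11).

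In GNLox 18 of the 32 lists pass for high against low light, 11 upwards and 7 downwards, with 3 under an estimated correlation and 29 by fry. CBF and COR rose for 9 of 9 (9 alone, median 4.36, adjusted p = 1.32e-17). ABA and dehydration rose for 15 of 15 (15 alone, median 3.75, adjusted p = 8.47e-23). Heat shock rose for 27 of 27 (27 alone, median 3.71, adjusted p = 5.42e-08, and adjusted p = 0.32 with an estimated correlation). Antioxidant enzymes rose for 15 and fell for 2 of 27 (15 and 2 alone, median 0.34, adjusted p = 0.000168, and adjusted p = 0.168 with an estimated correlation). Glucosinolate genes fell for 19 of 20 (19 alone, median -1.72, adjusted p = 5.42e-08, and adjusted p = 0.254 with an estimated correlation). All 22 cell cycle genes fell (22 alone, median -1.08, adjusted p = 2.33e-06, and adjusted p = 0.36 with an estimated correlation). Cytokinin response genes fell for 11 of 12 (11 alone, median -0.97, adjusted p = 0.00586, and adjusted p = 0.257 with an estimated correlation). Chlorophyll synthesis fell for 18 and rose for 3 of 24 (18 and 3 alone, median -0.42, adjusted p = 0.00423, and adjusted p = 0.527 with an estimated correlation). The antenna list (17 lower and 3 higher of 21, 17 and 3 alone, median -1.07, adjusted p = 0.000206, and adjusted p = 0.36 with an estimated correlation) holds LHCB4.1, which rose 2.69-fold (169 ± 9.8 against 62.7 ± 1.3 CPM, adjusted p = 2.53e-11). Chloroplast regulators have a median of -0.18 and a mean of 0.06 (3 higher and 4 lower of 8, 3 and 4 alone, adjusted p = 0.83). Nitrate assimilation has a median of -0.13 and a mean of -0.08 while its test points upwards (5 higher and 5 lower of 15, 5 and 5 alone, adjusted p = 0.671).

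Col-0 and GNLox share 4217 genes higher and 4826 genes lower in high light (2015 and 2392 by chance), 811 go opposite ways (4418 by chance), and the correlation is 0.746. Between hex and GNLox it is 0.734, with 607 genes in opposite directions (3720 by chance). In all 3 genotypes 3447 genes are higher and 3748 lower in high light.

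**Figure D3:**
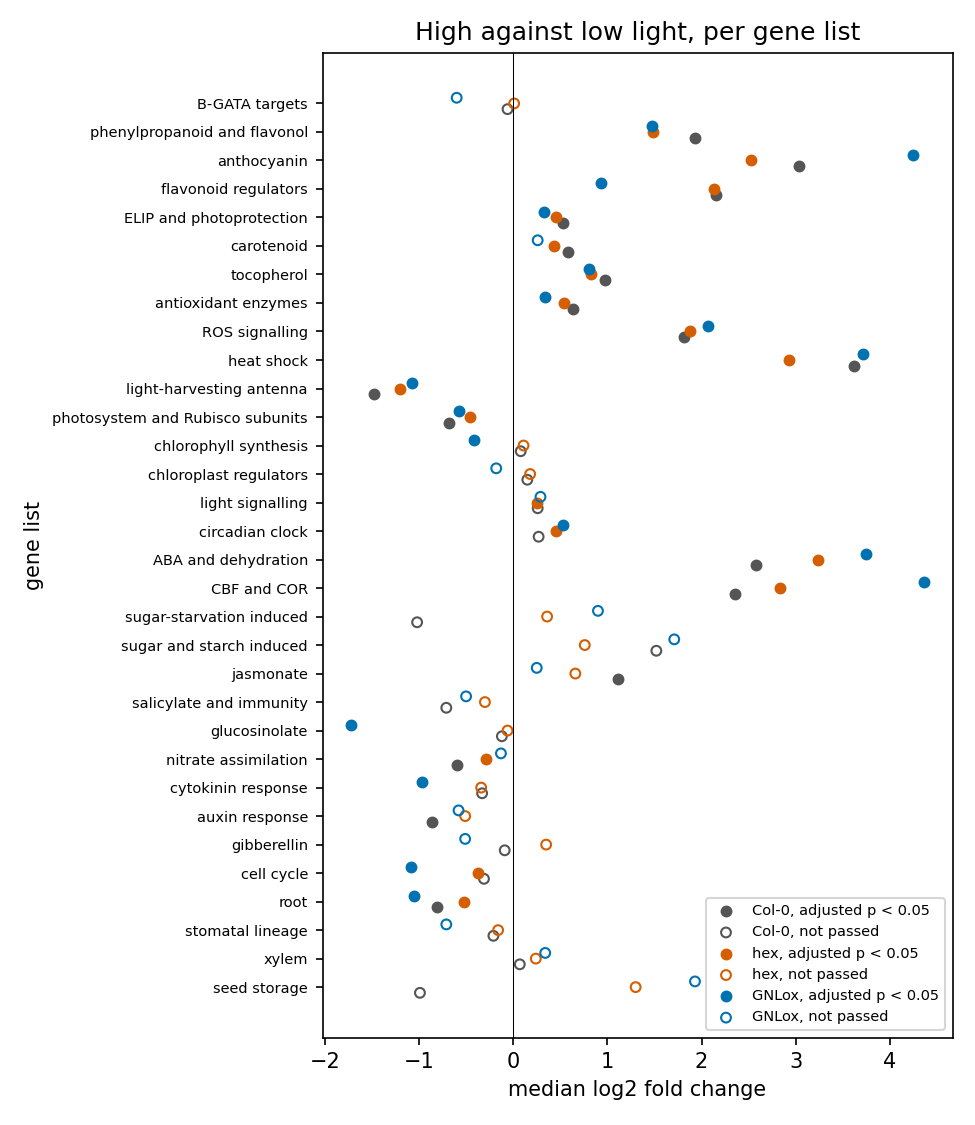
Median log2 fold change of each gene list, high against low light, in Col-0, hex and GNLox. Filled points pass an adjusted p under 0.05 by camera with a preset correlation of 0.01 between genes.

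After 6 h in low light few genes had moved from their level at t0, among them genes of the clock and of flavonols. PRR7, which codes for a clock repressor of the day phase, rose 2.11-fold in Col-0 (97.9 ± 7.6 against 46.3 ± 2.7 CPM, n = 3 and 3, adjusted p = 1.58e-06) and fell 1.49-fold in hex (45 ± 3.4 against 67.2 ± 10 CPM, adjusted p = 0.00491, 0.0604 without hex t0 replicate 3 and 0.231 with only the compared libraries), a difference between genotypes that was not tested as such. MYBL2, a repressor of flavonoid genes, rose 2.69-fold in Col-0 (26.3 ± 2.7 against 9.78 ± 1.6 CPM, adjusted p = 0.000342), and fell 1.87-fold in hex (adjusted p = 0.0378). In hex this is lost without hex t0 replicate 1 (0.0565) or 3 (0.288), without hex t6LL replicate 1 (0.0578), 2 (0.227) or 3 (0.164), and with only the compared libraries (0.241). LAC11, a laccase gene, rose 1.98-fold in hex (adjusted p = 0.000201) and 2.14-fold in GNLox (10.9 ± 0.9 against 5.1 ± 0.77 CPM, adjusted p = 0.000132), and with only the compared libraries neither passes (0.0865 and 0.0717). GNL passed no threshold between low light and t0 (adjusted p = 0.115 in Col-0, and 0.0246 without Col-0 t6LL replicate 3), and it has the smallest adjusted p of the 6 B-GATA genes in Col-0.

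In Col-0 537 genes are called between low light and t0, with 22 at 2-fold or more. The count is 321 without Col-0 t0 replicate 1, 197 without Col-0 t0 replicate 2, 178 without Col-0 t0 replicate 3, 81 without Col-0 t6LL replicate 2 and 335 without Col-0 t6LL replicate 3. In hex 67 genes are called, with 15 at 2-fold or more, and 30 without hex t0 replicate 3 or 42 without hex t6LL replicate 2. In GNLox 48 are called, with 26 at 2-fold or more, and 22 without GNLox t0 replicate 2 or 27 without GNLox t6LL replicate 2. Fitted on the compared libraries alone edgeR calls 65, 6 and 0 genes and DESeq2 711, 144 and 68, with 1184 under 0.05 before adjustment in GNLox. MYB111, a flavonol regulator, has the lowest fold change in Col-0 (log2 -1.32 ± 0.139, adjusted p = 1.75e-05), and LHCB4.3 fell 1.95-fold there (adjusted p = 0.000871). TGG4 and TGG5 are highest in hex (3.78-fold, adjusted p = 0.000169, and 3.45-fold, adjusted p = 0.000498) and in GNLox (3.39-fold, adjusted p = 0.000483, and 3.95-fold, adjusted p = 0.000199), where both have 0.0717 with only the compared libraries. Of their reads 86.4 and 87% are unique to 1 gene, so the 2 genes are not fully told apart.

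Of the 32 lists 17 pass in Col-0 (9 upwards and 8 downwards), 11 in hex (8 and 3) and 9 in GNLox (3 and 6). Under an estimated correlation 2, 2 and 1 pass, and by fry 8, 2 and 1. The ELIP and photoprotection list fell in Col-0 (5 of 11 lower, 8 alone, median -0.26, adjusted p = 1.08e-09), with OHP1 1.27-fold lower (adjusted p = 0.000871). Auxin response rose (1 of 10 higher, 5 alone, median 0.40, adjusted p = 2.25e-06), with IAA29 4.84-fold higher (adjusted p = 0.00182, and 0.0685 with only the compared libraries). Phenylpropanoid and flavonol genes fell in Col-0 (4 of 12 lower, 7 alone, median -0.22, adjusted p = 4.96e-08, and adjusted p = 0.121 with an estimated correlation) and rose in hex (4 of 12 higher, 11 alone, median 0.35, adjusted p = 3.22e-26). F3H is 1.43-fold higher in hex (adjusted p = 0.00352, and 0.151 with only the compared libraries). Xylem genes rose in hex (1 of 7, 7 alone, median 0.32, adjusted p = 2.77e-14) and in GNLox (5 of 7, 7 alone, median 0.49, adjusted p = 1.62e-29). XCP1 is 1.43-fold higher in GNLox (adjusted p = 0.00478, 0.0535 without GNLox t0 replicate 2 and 0.083 with only the compared libraries). Root markers also pass upwards, with 0 of 16 called and 0 alone, in Col-0 (median 0.21, adjusted p = 0.0128, and adjusted p = 0.34 with an estimated correlation, 0.438 without Col-0 t0 replicate 3 and 0.0649 without Col-0 t6LL replicate 2), in hex (median 0.22, adjusted p = 0.00211, and adjusted p = 0.265 with an estimated correlation, 0.0757 without hex t6LL replicate 3) and in GNLox (median 0.36, adjusted p = 1.58e-05, and adjusted p = 0.211 with an estimated correlation).

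In hex, most antenna, photosystem and chlorophyll synthesis genes are read below Col-0 at t0, though no such list passes with an estimated correlation. CRD1, which codes for a cyclase of chlorophyll synthesis, is 1.94-fold lower at t0 (753 ± 48 against 1460 ± 89 CPM, n = 3 and 3). PDS3, the phytoene desaturase gene of carotenoid synthesis, is 1.79-fold lower (78.3 ± 6.5 against 141 ± 2.8 CPM). LHCB1.1, an antenna gene of photosystem II, is 2.1-fold lower at t0 (1300 ± 60 against 2730 ± 630 CPM) and 3.3-fold lower in low light (1100 ± 140 against 3630 ± 210 CPM). GATA16 stays above Col-0 in low light (3.65-fold, adjusted p = 3e-08) and in high light (2.2-fold, adjusted p = 3.75e-06), and so does GATA15 (2.06-fold, adjusted p = 4.41e-05, and 1.81-fold, adjusted p = 0.000281). GATA17L is below Col-0 in both (1.79-fold, adjusted p = 1.26e-05, and 1.73-fold, adjusted p = 1.26e-05), and GNL is 1.62-fold above it in low light (22.2 ± 1.4 against 13.7 ± 3.5 CPM, adjusted p = 0.00184).

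Between hex and Col-0 6288 genes are called at t0 (3134 higher and 3154 lower in hex, 651 at 2-fold or more), 5470 in low light (2700 and 2770, 620 at 2-fold or more) and 8470 in high light (4285 and 4185, 777 at 2-fold or more). The same 1731 genes are higher and 1918 lower at both t0 and in low light, where 390 and 403 are given by chance. MRD1 has the highest fold change at t0 and in high light (log2 3.49 ± 0.714, adjusted p = 0.000666, and 9.17-fold higher, adjusted p = 7.5e-05), but 16.3% of its reads are unique to it, so its count is uncertain. PDF1.3, a defensin gene, follows at t0 (4.78-fold, 13.9 ± 1.3 against 2.89 ± 0.65 CPM, adjusted p = 0.00214) and is highest in low light (4.96-fold, adjusted p = 0.00188). ESM1, a gene for a modifier of glucosinolate breakdown, is 5.3-fold higher in hex in high light (1700 ± 300 against 320 ± 35 CPM, adjusted p = 1.86e-09). AT1G13650 has the lowest fold change at t0 and in low light (12.6-fold lower, adjusted p = 3.52e-11, and 9.44-fold lower, adjusted p = 3.46e-10). AGL87, a MADS-box gene, has the lowest in high light (6.81-fold lower, 3.46 ± 0.5 CPM in hex, adjusted p = 2.14e-13).

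At t0 12 of the 32 lists pass between hex and Col-0, 1 upwards and 11 downwards, with 2 under an estimated correlation and 15 by fry. Carotenoid genes are lower for 12 of 13 (13 alone, median -0.65, adjusted p = 3.41e-19), with PSY 1.65-fold lower (adjusted p = 8.88e-09). Tocopherol genes are lower for 6 of 6 (6 alone, median -0.48, adjusted p = 6.37e-05), with VTE1 1.79-fold lower (adjusted p = 1.7e-07). Photosystem and Rubisco subunits are lower for 30 of 31 (31 alone, median -0.57, adjusted p = 5.8e-26, and adjusted p = 0.0863 with an estimated correlation). RBCS3B is 1.86-fold lower (adjusted p = 1.05e-08), with 73.8% of its reads unique to it, and PSBQ1 is 1.74-fold lower (adjusted p = 1.51e-08). The antenna is lower for 20 of 21 genes (20 alone, median -0.65, adjusted p = 2.14e-17, and adjusted p = 0.0854 with an estimated correlation), with LHCA6 1.56-fold lower (adjusted p = 1.21e-07). Chlorophyll synthesis is lower for 19 of 24 (19 alone, median -0.42, adjusted p = 1.81e-14, and adjusted p = 0.0933 with an estimated correlation). ELIP and photoprotection is lower for 7 of 11 (8 alone, median -0.49, adjusted p = 1.65e-07, and adjusted p = 0.0854 with an estimated correlation), with OHP1 1.7-fold lower (adjusted p = 3.63e-10). The chloroplast regulators are lower for 7 of 8 (7 alone, median -0.43, adjusted p = 0.00014, and adjusted p = 0.0854 with an estimated correlation), with SIG2 1.43-fold lower (adjusted p = 3.39e-06). Xylem genes are lower for 6 of 7 (7 alone, median -0.32, adjusted p = 0.00876, and adjusted p = 0.438 with an estimated correlation). Root markers are lower for 6 of 16 (9 alone, median -0.54, adjusted p = 0.0458, and adjusted p = 0.544 with an estimated correlation), with 0.123 and 0.139 without Col-0 t0 replicate 1 or 2 and 0.0997 and 0.0601 without hex t0 replicate 1 or 2.

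In low light 12 lists pass between hex and Col-0, 3 upwards and 9 downwards (1 under an estimated correlation, 15 by fry), and in high light 11, 2 upwards and 9 downwards (15 by fry). With an estimated correlation the adjusted p of every list in high light is 0.195 or more. The antenna is lower in low light for 20 and higher for 1 of 21 genes (20 and 1 alone, median -1.05, adjusted p = 1.01e-41). LHCB1.2 is 2.98-fold lower (adjusted p = 2.27e-09) and LHCA4 2.43-fold lower (adjusted p = 1.88e-08). In high light it is lower for 19 of 21 (19 alone, median -0.65, adjusted p = 5.89e-16, and adjusted p = 0.195 with an estimated correlation). Phenylpropanoid and flavonol genes are higher in hex in low light for 7 of 12 (7 alone, median 0.35, adjusted p = 8.66e-06, and adjusted p = 0.316 with an estimated correlation), with 4CL3 1.92-fold higher (adjusted p = 5.01e-07). At t0 they are lower for 6 of 12 (6 alone, median -0.23, adjusted p = 0.0248, and adjusted p = 0.742 with an estimated correlation), with 0.0539 and 0.139 without Col-0 t0 replicate 1 or 2 and 0.0736 without hex t0 replicate 1. Light signalling is higher in hex in high light for 10 and lower for 1 of 18 (12 and 1 alone, median 0.23, adjusted p = 0.000322, and adjusted p = 0.195 with an estimated correlation). Sugar-starvation genes are higher for 9 of 9 in high light (9 alone, median 0.96, adjusted p = 0.0206, and adjusted p = 0.749 with an estimated correlation). Without hex t6HL replicate 2 the list value is 0.0643 and without hex t6HL replicate 3 it is 0.0965, so this call rests on these 2 libraries. In low light the flavonoid regulators hold MYB111 at 3.03-fold higher (adjusted p = 3.3e-08) and MYBL2 at 3.13-fold lower (adjusted p = 1.37e-06), and the list does not pass (3 higher and 1 lower of 11, 5 and 1 alone, median 0.59, adjusted p = 0.238).

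In GNLox, most genes of the glucosinolate, phenylpropanoid and root marker lists are read below Col-0 before treatment, though no list passes with an estimated correlation, and 1 antenna gene stands far below its paralogs. LHCB4.1, which codes for a minor antenna protein of photosystem II, is 36.6-fold lower at t0 (69.1 ± 10 against 2530 ± 300 CPM, n = 3 and 3, adjusted p = 5.12e-19), 42.2-fold lower in low light (adjusted p = 2.72e-19) and 10.5-fold lower in high light (adjusted p = 4.12e-16). NRT2.1, a high-affinity nitrate transporter gene, is 36-fold lower at t0 (0.228 ± 0.054 against 8.4 ± 1.2 CPM, adjusted p = 1.29e-09), and NIA1, a nitrate reductase gene, is 4.6-fold higher (783 ± 140 against 170 ± 3.1 CPM, adjusted p = 2.61e-10). GATA16 is 10.7-fold lower at t0 (adjusted p = 1.33e-10), 5.7-fold in low light (adjusted p = 1.38e-09) and 14.2-fold in high light (adjusted p = 4.52e-12). GNC is 9.84-fold lower (adjusted p = 6.06e-10), 6.53-fold lower (adjusted p = 6.77e-09) and 6.72-fold lower (adjusted p = 7.83e-09) in the same order.

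Between GNLox and Col-0 14273 genes are called at t0 (7250 higher and 7023 lower in GNLox, 3677 at 2-fold or more), 14219 in low light (7155 and 7064, 3552 at 2-fold or more) and 13862 in high light (6622 and 7240, 4196 at 2-fold or more). The same 6231 genes are higher and 6252 lower at both t0 and in low light (2392 and 2287 by chance). MRD1 is above GNL in fold change at t0 (log2 9.05 ± 0.407, 27.1 ± 0.94 against 0.0459 ± 0.057 CPM, adjusted p = 2e-13), with the uncertainty given above. CAD8 (log2 6.86 ± 1.586, adjusted p = 0.000666), HSP17.4 (5.40 ± 1.468, adjusted p = 0.00274) and AT3G02480 (4.57 ± 0.462, 89.5 ± 13 against 3.75 ± 1.6 CPM, adjusted p = 1.8e-08) follow. The lowest at t0 are AT2G19970 (168-fold lower, adjusted p = 3e-11), MES18 (108-fold lower, adjusted p = 5.68e-11) and GSTF14 (83.5-fold lower, 0.581 ± 0.14 against 48.3 ± 3.9 CPM, adjusted p = 1.6e-10). In high light DIR1_2 is at least 92.8-fold higher in GNLox, with 0 counts in Col-0, and it is uncertain as above. BGLU30 is 25.2-fold higher there (122 ± 48 against 4.77 ± 1.5 CPM, adjusted p = 4.03e-07), and SEN1, a senescence gene, 19.1-fold higher (66.5 ± 23 against 3.37 ± 2.5 CPM, adjusted p = 2.86e-06).

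Of the 32 lists 9 pass between GNLox and Col-0 at t0 (2 upwards and 7 downwards), 11 in low light (3 and 8) and 13 in high light (6 and 7), and by fry 20, 17 and 22. With an estimated correlation the smallest adjusted p of a list is 0.265 at t0, 0.451 in low light and 0.0989 in high light. Xylem genes are lower for 7 of 7 at t0 (7 alone, median -0.98, adjusted p = 1.05e-06, and adjusted p = 0.265 with an estimated correlation). Root markers are lower for 13 of 16 (13 alone, median -1.66, adjusted p = 0.000986, and adjusted p = 0.43 with an estimated correlation), with COBL9 4.02-fold lower (adjusted p = 2.28e-08). Phenylpropanoid and flavonol genes are lower for 11 of 12 at t0 (11 alone, median -1.14, adjusted p = 1.24e-09, and adjusted p = 0.265 with an estimated correlation). FLS1 is 3.8-fold lower (adjusted p = 2.64e-13) and CHS 3.53-fold lower (192 ± 25 against 676 ± 71 CPM, adjusted p = 1.17e-12). Nitrate assimilation is lower for 9 and higher for 1 of 15 (9 and 1 alone, median -0.55, adjusted p = 0.012, and adjusted p = 0.642 with an estimated correlation). Cytokinin response is lower for 9 of 12 (10 alone, median -0.75, adjusted p = 0.00352, and adjusted p = 0.451 with an estimated correlation). Glucosinolate genes are lower at t0 for 18 and higher for 1 of 20 (18 and 1 alone, median -1.10, adjusted p = 0.000165, and adjusted p = 0.642 with an estimated correlation). In high light 19 of 20 are lower and 1 higher (19 and 1 alone, median -2.11, adjusted p = 4.08e-15, and adjusted p = 0.156 with an estimated correlation). CYP79B3 is 5.95-fold lower (adjusted p = 4.69e-12).

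In GNLox most chlorophyll and carotenoid genes lie above Col-0 at t0 and anthocyanin genes below. Chlorophyll synthesis is higher than in Col-0 for 18 and lower for 1 of 24 genes at t0 (18 and 1 alone, median 0.36, adjusted p = 0.0019, and adjusted p = 0.772 with an estimated correlation). CHLD is 1.56-fold higher (431 ± 1.8 against 276 ± 16 CPM, adjusted p = 9.92e-08) and PORB 1.94-fold higher (adjusted p = 1.17e-07). Carotenoid genes are higher for 11 of 13 (11 alone, median 0.34, adjusted p = 0.00352, and adjusted p = 0.642 with an estimated correlation), with PDS3 1.58-fold higher (adjusted p = 2.63e-09). Anthocyanin genes are lower for 7 of 7 (7 alone, median -2.37, adjusted p = 0.00352, and adjusted p = 0.642 with an estimated correlation). The antenna at t0 has 13 genes higher and 2 lower of 21 (14 and 2 alone, median 0.30, adjusted p = 0.725), with LHCB1.2 1.88-fold higher (adjusted p = 3.11e-07). In high light the sugar-starvation genes are higher for 9 of 9 (9 alone, median 1.99, adjusted p = 0.000361, and adjusted p = 0.446 with an estimated correlation). Cell cycle genes are lower for 21 of 22 (21 alone, median -0.77, adjusted p = 0.000598, and adjusted p = 0.553 with an estimated correlation), with CDKB2;1 2.27-fold lower (adjusted p = 5.23e-07). At t0 seed storage has 5 of 5 genes higher (5 alone) and a median of 3.17, or 3.41 when genes at or under the floor take their bound, without passing as a list (adjusted p = 0.363). At t0 the antenna mean is 0.00, the ELIP and photoprotection list has a median of 0.20 and a mean of -0.04 (7 higher and 3 lower of 11, 7 and 3 alone, adjusted p = 0.725). The cell cycle list has a median of -0.02 and a mean of -0.01 while its test points upwards (4 higher and 2 lower of 22, 3 and 0 alone, adjusted p = 0.794).

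**Figure D4:**
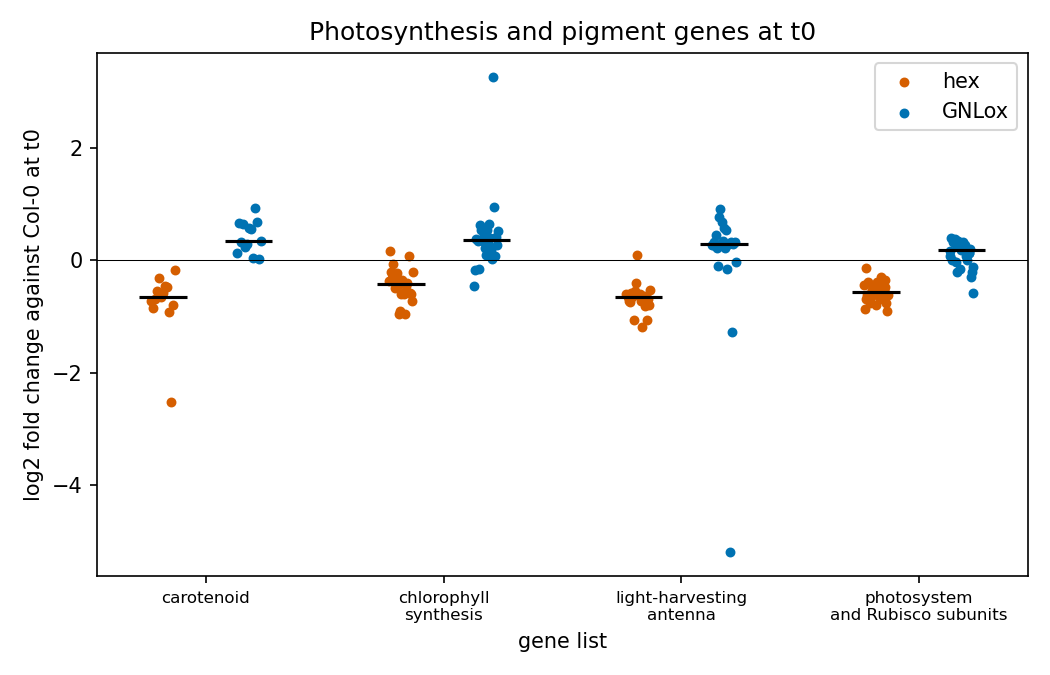
Log2 fold change against Col-0 of each gene of 4 lists (carotenoid, chlorophyll synthesis, light-harvesting antenna, photosystem and Rubisco subunits) at t0, in hex and in GNLox. Bars mark the list medians.

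In hex the high-light response of single genes differs from that in Col-0, while with an estimated correlation no gene list does. SEN1, a gene induced in dark and starvation, goes from 3.58 ± 0.61 CPM in low light to 16.1 ± 12 CPM in high light in hex, and from 7.25 ± 1.6 to 3.37 ± 2.5 CPM in Col-0 (n = 3 in each group, difference of responses log2 3.23 ± 0.866, adjusted p = 0.0229). Its adjusted p is 0.0624 without Col-0 t6LL replicate 2, 0.0618 without hex t6LL replicate 2, 0.067 without Col-0 t6HL replicate 2, 0.054 without Col-0 t6HL replicate 3, 0.0695 without hex t6HL replicate 3 and 0.0776 with only the compared libraries. LHCB2.3, an antenna gene, goes from 224 ± 31 to 37.7 ± 6.4 CPM in hex and from 710 ± 91 to 58.9 ± 5.9 CPM in Col-0 (difference 1.02 ± 0.238, adjusted p = 0.0103). MYB75, an anthocyanin regulator, goes from 4.32 ± 1.1 to 42.3 ± 14 CPM in hex and from 1.84 ± 0.43 to 53.8 ± 2.6 CPM in Col-0 (difference -1.58 ± 0.396, adjusted p = 0.0159, and 0.058 without Col-0 t6LL replicate 2). GATA16 has a difference of -0.73 ± 0.22 (adjusted p = 0.0444), and its adjusted p lies between 0.0585 and 0.125 without any 1 of the 12 libraries except hex t6LL replicate 3 and hex t6HL replicate 1.

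The high-light response differs between hex and Col-0 for 1679 genes (749 more positive and 930 more negative in hex, 187 at 2-fold or more). The count is 1029 without Col-0 t6LL replicate 2, 1074 without hex t6LL replicate 2, 1098 without Col-0 t6HL replicate 2 and 2696 without hex t6HL replicate 1. The most positive differences after SEN1 are PEX3_2 (3.14 ± 0.632, adjusted p = 0.00374), AT3G15450 (2.73 ± 0.625, 51.5 ± 4.6 to 89.5 ± 62 CPM in hex and 130 ± 26 to 33.8 ± 23 CPM in Col-0, adjusted p = 0.00893), DRMH1 (2.56 ± 0.513, adjusted p = 0.0037) and AT1G80440 (2.25 ± 0.494, adjusted p = 0.00671). With only the compared libraries AT3G15450 (0.0785) and AT1G80440 (0.0605) do not pass. The most negative include BOR5 (-1.65 ± 0.247, 10.6 ± 3.4 to 14.5 ± 1.3 CPM in hex and 8.75 ± 0.79 to 37.5 ± 6 CPM in Col-0, adjusted p = 0.000338), LTP3 (-1.48 ± 0.316, adjusted p = 0.00572) and LOX3, a jasmonate synthesis gene (-1.40 ± 0.266, adjusted p = 0.00257).

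Of 32 lists 10 pass for the hex difference (7 upwards and 3 downwards), 6 by fry and 0 with an estimated correlation, where the smallest adjusted p is 0.173. Light signalling has 7 of 18 genes more positive in hex (10 alone, median 0.39, adjusted p = 4.1e-06, and adjusted p = 0.173 with an estimated correlation), with CRY1, a blue-light receptor gene, at 0.58 ± 0.073 (adjusted p = 9.26e-05). The sugar-starvation genes have 7 of 9 more positive (7 alone, median 1.29, adjusted p = 1.72e-06, and adjusted p = 0.343 with an estimated correlation). AKINBETA1 is at 1.11 ± 0.238 (adjusted p = 0.00581, and 0.0526 with only the compared libraries). The sugar and starch list has 2 of 6 more negative (4 alone, median -0.76, adjusted p = 0.0083, and adjusted p = 0.343 with an estimated correlation), with APL3, a starch synthesis gene, at -0.88 ± 0.2 (adjusted p = 0.00829, and 0.0572 with only the compared libraries). The circadian clock has 2 of 16 more positive (3 alone, median 0.19, adjusted p = 0.00521, and adjusted p = 0.343 with an estimated correlation). RVE1 is at 1.48 ± 0.251 (adjusted p = 0.00107). Auxin response has 3 of 10 more positive (3 alone, median 0.40, adjusted p = 0.00445, and adjusted p = 0.343 with an estimated correlation).

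For 5 lists the hex difference depends on single libraries. The antenna has 3 of 21 genes more positive (3 alone, median 0.25, adjusted p = 0.00453, and adjusted p = 0.735 with an estimated correlation), and its adjusted p is 0.0942 without hex t6HL replicate 1. Photosystem and Rubisco subunits have 4 of 31 more positive (6 and 2 negative alone, median 0.18, adjusted p = 0.00453, and adjusted p = 0.754 with an estimated correlation). PETE1 is at 0.54 ± 0.11 (adjusted p = 0.00392). The list reaches 0.166 without Col-0 t6LL replicate 1 and 0.47 without hex t6HL replicate 1. Heat shock genes have 1 of 27 more negative (1 alone, median -0.51, adjusted p = 0.00506, and adjusted p = 0.735 with an estimated correlation), CLPB3 (-0.50 ± 0.11, adjusted p = 0.00654). That list reaches 0.0644 without Col-0 t6HL replicate 1 and 0.487 without hex t6HL replicate 1. Phenylpropanoid and flavonol genes have 5 of 12 more negative (7 and 2 positive alone, median -0.31, adjusted p = 0.0083, and adjusted p = 0.735 with an estimated correlation). UGT78D1 is at -0.78 ± 0.165 (adjusted p = 0.0051). This list reaches 0.145 without hex t6LL replicate 3 and 0.0799 without hex t6HL replicate 2. Xylem genes have 1 of 7 more positive (4 alone, median 0.26, adjusted p = 0.0083, and adjusted p = 0.597 with an estimated correlation), and reach 0.0503 without hex t6LL replicate 3.

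In GNLox most cold and dehydration genes have a more positive high-light response than in Col-0, and most glucosinolate and cell cycle genes a more negative one. ERD10, a dehydrin gene, goes from 27.8 ± 2.3 to 782 ± 51 CPM in GNLox and from 87.1 ± 11 to 329 ± 38 CPM in Col-0 (n = 3 in each group, difference 2.89 ± 0.232, adjusted p = 2.59e-08). CYP79B3, which acts in indole glucosinolate synthesis, goes from 60.9 ± 4.4 to 13.2 ± 3 CPM in GNLox and from 78.6 ± 3 to 78.6 ± 10 CPM in Col-0 (difference -2.20 ± 0.201, adjusted p = 1.04e-07). Of the B-GATA genes, GATA17 has a difference of -0.92 ± 0.178 (adjusted p = 0.000351), GATA16 of -1.32 ± 0.34 (adjusted p = 0.004) and GATA17L of -0.58 ± 0.166 (adjusted p = 0.0081). GNL has -0.59 ± 0.207 (adjusted p = 0.028) and GATA15 has -0.77 ± 0.274 (adjusted p = 0.0289), and GNC passed no threshold (adjusted p = 0.939).

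The high-light response differs between GNLox and Col-0 for 8906 genes (3753 more positive and 5153 more negative in GNLox, 1828 at 2-fold or more). DIR1_2 and ADT6 are among the most positive, and both are uncertain, DIR1_2 as above and ADT6 because 0.016% of its reads are unique to it. BGLU30 has a difference of 6.07 ± 0.862 (2.08 ± 0.68 to 122 ± 48 CPM in GNLox and 5.49 ± 0.54 to 4.77 ± 1.5 CPM in Col-0, adjusted p = 1.35e-05), ERF053 of 5.29 ± 1.019 (adjusted p = 0.000329) and GAT1_2.1 of 4.77 ± 0.651 (adjusted p = 8.57e-06). The most negative include DIR13 (-3.53 ± 0.329, 3.37 ± 0.33 to 0.251 ± 0.099 CPM in GNLox and 13.6 ± 1.4 to 11.8 ± 0.76 CPM in Col-0, adjusted p = 1.22e-07), AT5G38820 (-2.65 ± 0.577, adjusted p = 0.000993) and IRT2, a root iron transporter gene (-2.63 ± 0.557, adjusted p = 0.000785).

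Of 32 lists 16 pass for the GNLox difference (9 upwards and 7 downwards), 19 by fry, and 1 also with an estimated correlation. That list is CBF and COR, with 7 of 9 genes more positive (7 alone, median 1.99). Its adjusted p is 1.58e-09, and 0.0264 with an estimated correlation. COR6.6 is at 1.90 ± 0.16 (adjusted p = 4.36e-08). It starts lower in GNLox in low light (11.5 against 42.7 CPM in Col-0) and ends alike in high light (220 against 219). ABA and dehydration has 13 of 15 more positive (13 alone, median 1.07, adjusted p = 2.37e-07, and adjusted p = 0.279 with an estimated correlation). RD29A is at 3.02 ± 0.343 (adjusted p = 1.11e-06) and ABI1 at 1.07 ± 0.139 (adjusted p = 5.03e-06). The antenna has 14 more positive and 2 more negative of 21 (14 and 2 alone, median 0.49, adjusted p = 1.02e-05, and adjusted p = 0.426 with an estimated correlation). LHCB4.1 is at 2.01 ± 0.136 (adjusted p = 3.46e-09). Nitrate assimilation has 9 of 15 more positive (9 alone, median 0.41, adjusted p = 0.000101, and adjusted p = 0.279 with an estimated correlation). NIR1 is at 1.47 ± 0.138 (adjusted p = 1.22e-07). ROS signalling has 5 more positive and 1 more negative of 15 (5 and 1 alone, median 0.68, adjusted p = 0.0102, and adjusted p = 0.523 with an estimated correlation). BAP1 is at 2.97 ± 0.278 (adjusted p = 1.22e-07).

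Among the lists with a more negative response in GNLox, glucosinolate genes have 18 of 20 (18 and 1 positive alone, median -1.41, adjusted p = 2.07e-10, and adjusted p = 0.279 with an estimated correlation). Cell cycle genes have 17 of 22 (19 alone, median -0.90, adjusted p = 8.65e-07, and adjusted p = 0.479 with an estimated correlation), with MCM5, a replication helicase gene, at -0.94 ± 0.129 (adjusted p = 9.37e-06). Chlorophyll synthesis has 17 more negative and 3 more positive of 24 (18 and 3 alone, median -0.48, adjusted p = 0.000305, and adjusted p = 0.491 with an estimated correlation). GSA1 is at -0.62 ± 0.093 (adjusted p = 2.66e-05) and HEMA2 at 1.22 ± 0.15 (adjusted p = 2.88e-06). Carotenoid genes have 8 more negative and 1 more positive of 13 (9 and 2 alone, median -0.32, adjusted p = 0.0244, and adjusted p = 0.491 with an estimated correlation). LUT1 is at -0.86 ± 0.096 (adjusted p = 9.15e-07). Cytokinin response has 7 more negative and 1 more positive of 12 (7 and 1 alone, median -0.56, adjusted p = 0.0251, and adjusted p = 0.426 with an estimated correlation), and reaches 0.0553 without GNLox t6LL replicate 3. The heat shock list has 2 more positive and 1 more negative of 27 (2 positive alone), a median of -0.18 and a mean of -0.37, while its test points upwards (adjusted p = 0.945).

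**Figure D5:**
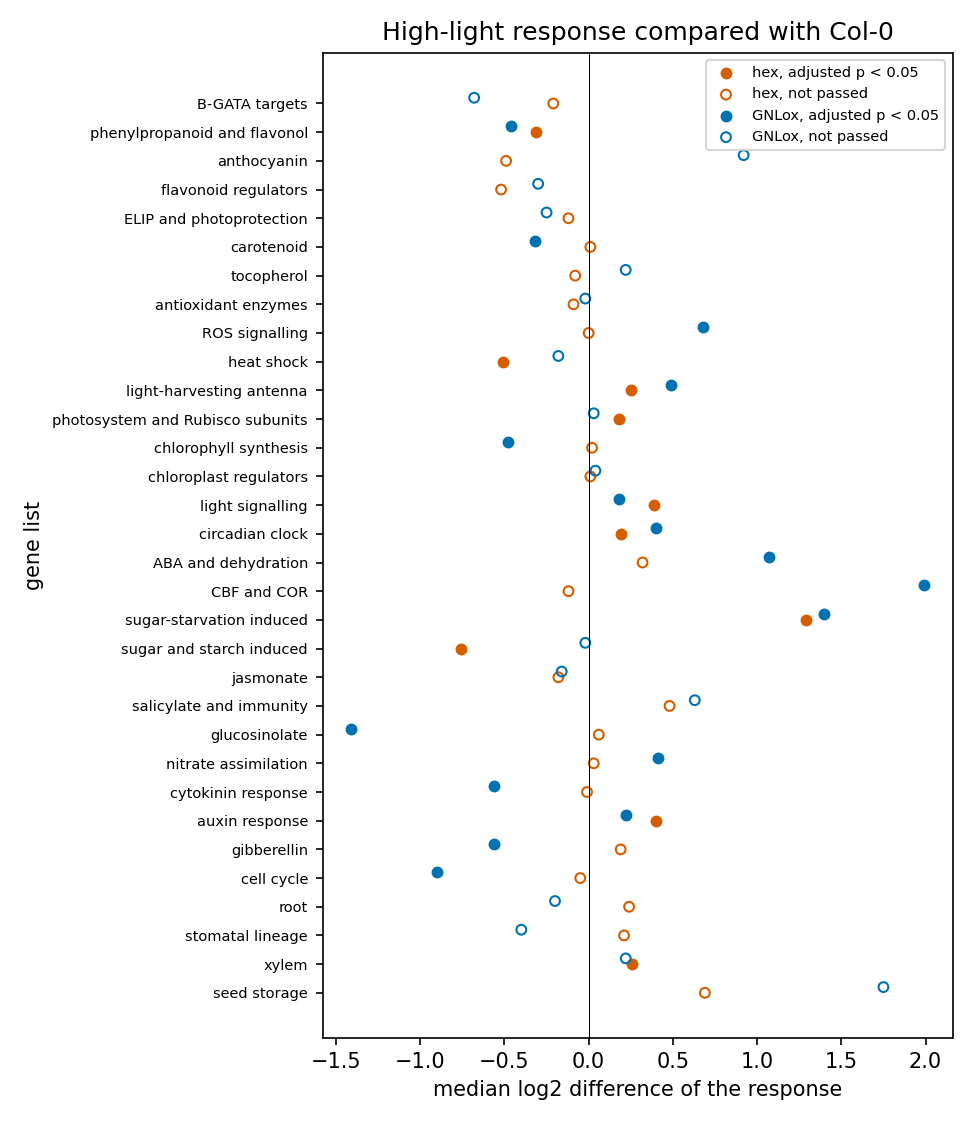
Median log2 difference of the high-light response from Col-0 for each of the 32 tested lists, in hex and in GNLox. Filled marks are lists with an adjusted p under 0.05.

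Many genes differ from Col-0 in opposite directions in the 2 lines. PDS3, the phytoene desaturase gene, is 1.79-fold lower in hex and 1.58-fold higher in GNLox at t0 (n = 3 in each group). At t0 1787 genes are higher in hex and lower in GNLox and 1983 lower in hex and higher in GNLox, where independent calls would give 1015 and 1054. In the same direction there are 447 higher and 520 lower (1048 and 1021 from independent calls). In low light the opposite groups have 1655 and 1871 genes (879 and 914) and the same-direction groups 300 and 414 (891 and 902), and in high light 2091 and 1725 (1430 and 1278) and 1001 and 677 (1308 and 1397). The correlation of the hex and GNLox differences across genes is -0.087 at t0, -0.133 in low light and -0.067 in high light. The covariances are -0.044, -0.064 and -0.038, and the shared Col-0 libraries alone give 0.0348, 0.035 and 0.0366 in simulated counts. The rank correlation is -0.241, -0.28 and -0.174. Without the count filter the Pearson value is 0.107, 0.078 and 0.117, so its sign depends on whether genes with few counts are kept. Whichever Col-0 library is left out, the Pearson value rises, to at most 0.006 at t0, 0.022 in low light and 0.046 in high light. The rank correlation then stays between -0.315 and -0.096.

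The differences of the high-light response in the 2 lines correlate at 0.293 across genes (jackknife standard error 0.076 over Col-0 libraries only). The covariance is 0.12, against 0.0718 from the shared libraries alone in simulated counts. In both lines 303 genes have a more positive and 566 a more negative response than Col-0 (130 and 221 from independent calls). In opposite directions 82 genes are more positive in hex and more negative in GNLox, and 56 the reverse (178 and 161). The shared Col-0 libraries alone can raise same-direction counts and lower opposite ones. AKINBETA1 and CRY1 are among the genes more positive in both lines (1.29 ± 0.235 and 0.43 ± 0.073 in GNLox, adjusted p = 0.000197 and 9.02e-05). UGT78D1 is among those more negative in both (-1.04 ± 0.168 in GNLox, adjusted p = 5.59e-05).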

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

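Of the tests in this part, all but 2 (the neighbours of LHCB4.1 and the admixture of low-light RNA) were chosen only after the result was seen.

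The high-light response differs between groups by a test of the difference itself for 1679 genes in hex and 8906 genes in GNLox. Fitted on the compared libraries alone, the hex difference has 922 genes, and 5 of 100 splits of the 12 libraries give as many or more, the real one included, with 2893 as the highest other. For GNLox the real split has 9174 genes and 1 of 100 splits gives as many, with 6212 as the highest other. Splits that part the genotypes unevenly bring the genotype effect into the difference. In each line the 40 others that part them evenly have 0 genes by edgeR, but mix both genotypes within each group, which widens its spread. These splits cannot decide on chance for either count.

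In hex the response also differs by this test, on the log2 scale, for SEN1 (3.23), PEX3_2 (3.14), AT3G15450 (2.73), DRMH1 (2.56), AT1G80440 (2.25), RVE1 (1.48), AKINBETA1 (1.11), LHCB2.3 (1.02), CRY1 (0.58), PETE1 (0.54), BOR5 (-1.65), MYB75 (-1.58), LTP3 (-1.48), LOX3 (-1.40), APL3 (-0.88), UGT78D1 (-0.78), GATA16 (-0.73) and CLPB3 (-0.50). Lists that differ are sugar-starvation (adjusted p = 1.72e-06), light signalling (4.1e-06), auxin response (0.00445), antenna and photosystem subunits (0.00453 each), heat shock (0.00506), circadian clock (0.00521), and phenylpropanoid, sugar and starch and xylem genes (0.0083 each), by camera. In GNLox the genes are BGLU30 (6.07), ERF053 (5.29), ADT6 (4.78, uncertain), GAT1_2.1 (4.77), RD29A (3.02), BAP1 (2.97), ERD10 (2.89), LHCB4.1 (2.01), COR6.6 (1.90), NIR1 (1.47), AKINBETA1 (1.29), HEMA2 (1.22), ABI1 (1.07), CRY1 (0.43), DIR13 (-3.53), AT5G38820 (-2.65), IRT2 (-2.63), CYP79B3 (-2.20), GATA16 (-1.32), UGT78D1 (-1.04), MCM5 (-0.94), GATA17 (-0.92), LUT1 (-0.86), GSA1 (-0.62) and GATA17L (-0.58). Its lists are glucosinolate (adjusted p = 2.07e-10), CBF and COR (1.58e-09), ABA (2.37e-07), cell cycle (8.65e-07), antenna (1.02e-05), sugar-starvation (1.21e-05), nitrate (0.000101), chlorophyll synthesis (0.000305), phenylpropanoid (0.00525), auxin (0.00715), ROS signalling (0.0102), circadian clock (0.0107), carotenoid (0.0244), and light signalling, cytokinin and gibberellin (0.0251 each). With an estimated correlation only CBF and COR in GNLox passes.

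In data that no comparison uses, the reads outside the listed genes, GNLox stands above Col-0 at t0 and in high light. Their share is 7.36 ± 2.25% in GNLox in high light against 2.75 ± 0.323% in Col-0, and 4.15 ± 0.779% against 2.12 ± 0.0595% at t0 (mean and SD of 3 libraries), while in low light the groups overlap (3.7 ± 0.559% against 3.09 ± 0.506%). No explanation of it was tested.

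For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. The real split and the highest other have, for high against low light, 13097 and 0 genes in Col-0, 8603 and 0 in hex, and 14124 and 0 in GNLox. For low light against t0 they have 65 and 4 in Col-0, 6 and 0 in hex, and 0 and 1 in GNLox. For hex against Col-0 they have 4896 and 0 at t0, 5212 and 0 in low light, and 6260 and 1 in high light, and for GNLox against Col-0 13618 and 0, 14397 and 0, and 13530 and 0. The real split is the highest of the 10, except for low light against t0 in GNLox, where all reach its count. Other splits mix the compared groups, which widens their spread, so their low counts cannot decide.

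The libraries labelled hex keep reads of the B-GATA genes, and 2 technical explanations are argued against. With reads unique to 1 gene, the 4 genes that differ from Col-0 still do (GATA16 2.01 ± 0.161, GATA15 1.06 ± 0.159, GATA17L -0.75 ± 0.115, GNC -0.80 ± 0.226, with 0.75 as the smallest size), so reads shared between paralogs are not the whole cause. A swap of single libraries between Col-0 and hex would put a library on the other side, and 0 of 18 libraries lie there. An exchange of whole groups, transcripts that are made but truncated, and a genotype other than the label stay open and were not tested.

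LHCB4.1 reads are low in GNLox at each time. If its reads had gone to its paralogs, the sum of LHCB4.1, LHCB4.2 and LHCB4.3 would match Col-0, but it is 0.409 ± 0.0315 of it at t0, 0.344 ± 0.028 in low light and 0.28 ± 0.0101 in high light. Of 14 genes within 20 kb, 0 fell at least 2-fold by edgeR. As 12.2% of all genes did and the chance of 0 is 0.162, this cannot decide on a local effect. The 14 log2 fold changes lie between -0.64 and 1.51, so none fell like LHCB4.1. A variant or insertion in this gene alone, and an effect of the transgene product, also stay open and were not tested.

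In hex t6HL replicate 1 the high-light response is weaker than in the other 2 libraries (PC1 -15.95 against 13.82 and 7.38). Admixed low-light RNA would shift genes that rise and fall by the same share, but the shares are 0.502 from 182 rising and 0.0489 from 148 falling genes, a difference of 0.453 with a bootstrap standard error of 0.0454. The same difference is -0.318 and -0.154 in replicates 2 and 3. A low-light library with the high-light label would lie closer to low light for most genes, but 12.3% of 350 genes do. A first form of the depth test, whether the library holds the fewest exon reads of the 3, went with lower depth (34951564 against 38335172 and 42291249) but could not decide. It was replaced after its result was seen by thinning the other 2 libraries to this depth, where the share from rising genes stays at 0.504, so lower depth is argued against. Harvest or light exposure of this sample may have differed, which was not tested.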

How the results depend on the processing

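The alternatives with total gene reads, with GNLox t6LL replicate 3 and hex t6HL replicate 1 left out, with the rank correlation, and those of the correlations other than DESeq2 size factors and called genes were chosen only after the result was seen.

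Counts of genes stayed within 1.5 times in all 14 comparisons with DESeq2 size factors, with no filter and with the stricter filter, with unique reads, total gene reads, without organelle genes, and with the replicate block. Replicate numbers do not pair the libraries: residuals of libraries with the same number correlate at -0.012 on average (-0.352 to 0.342), and those with different numbers at 0.006. With the replicate block, 12 lists pass for the hex difference of responses, against 10, and 12 for GNLox against Col-0 in high light, against 13, where CBF and COR is lost (adjusted p = 0.051).

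With a 2-fold threshold the counts are, by construction, lower: 3409, 2534 and 4804 for high against low light in Col-0, hex and GNLox, 22, 15 and 26 for low light against t0, 651, 620 and 777 for hex against Col-0 at t0, in low and in high light, 3677, 3552 and 4196 for GNLox, and 187 and 1828 for the differences of responses. With only the compared libraries low light against t0 has 65 genes in Col-0, 6 in hex and 0 in GNLox by edgeR's quasi-likelihood test and 711, 144 and 68 by the DESeq2 Wald test, with 1184 under 0.05 before adjustment in GNLox. The hex difference has 922. Of the named genes 15 calls are lost there (values beside these genes above). GATA16 is lost for that difference with DESeq2 size factors (0.0527), no filter (0.0534), the stricter filter (0.0531) and the replicate block (0.0534), MYBL2 in hex in low light against t0 with the replicate block (0.0603), and GNL in hex in high light without the 2 libraries (0.113). By the DESeq2 Wald test low light against t0 has 174 genes in hex, and without the 2 libraries the hex difference has 2723, and the cause was not tested.

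With an estimated correlation the lists that pass number 7, 7 and 3 for high against low light in Col-0, hex and GNLox, 2, 2 and 1 for low light against t0, 2, 1 and 0 for hex against Col-0 at t0, in low and in high light, 0, 0 and 0 for GNLox, and 0 and 1 for the differences. By fry 29 pass for high light in GNLox, 8, 2 and 1 for low light against t0, 20, 17 and 22 for GNLox against Col-0, and 6 for the hex difference, and the cause was not tested.

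The correlation of the hex and GNLox effects reverses without the filter (0.107 at t0, 0.078 in low light, 0.117 in high light) and in high light without the 2 libraries (0.019). It moves to -0.135 over called genes, -0.18, -0.234 and -0.124 with the stricter filter, -0.172 with only the compared libraries at t0 and -0.123 with unique reads at t0. By rank it moves to -0.132, -0.161 and -0.07 without the filter, and without the 2 libraries to -0.063 in high light and 0.386 for the responses. The cause was not tested. With total gene reads GATA17 (0.01) and GNL (0.08), not called in hex at t0, change sign.

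Leaving out 1 library at a time, the counts of genes range over 12091 to 12488, 9489 to 11436 and 13647 to 13888 for high against low light in Col-0, hex and GNLox, 81 to 444, 30 to 83 and 22 to 37 for low light against t0, 5201 to 5664, 4246 to 4776 and 7118 to 8403 for hex against Col-0 at t0, in low and in high light, 13109 to 13675, 12994 to 13672 and 12916 to 13233 for GNLox, and 1029 to 2696 and 7514 to 8845 for the differences. The counts of lists range over 17 to 19, 19 to 20 and 18 to 20 for high against low light in Col-0, hex and GNLox, 10 to 18, 10 to 15 and 10 to 12 for low light against t0, 9 to 13, 9 to 13 and 9 to 14 for hex against Col-0 at t0, in low and in high light, 9 to 9, 10 to 11 and 10 to 15 for GNLox, and 9 to 12 and 15 to 17 for the differences. With only Col-0 libraries left out, the correlations range over -0.025 to 0.006, -0.105 to 0.022, -0.044 to 0.046 and 0.292 to 0.399 at t0, in low and high light and for the responses. By rank they range over -0.261 to -0.175, -0.315 to -0.167, -0.185 to -0.096 and 0.243 to 0.376. For low light against t0 in Col-0, 2 list calls reverse without Col-0 t6LL replicate 3 (photosystem subunits, adjusted p = 0.786, range 1.84e-08 to 0.786, and salicylate, 0.151, range 9.64e-06 to 0.711). In hex at t0 GATA17 changes sign without Col-0 t0 replicate 3 (0.10), hex t0 replicate 1 (0.00) and hex t0 replicate 3 (0.04), with a range of -0.11 to 0.10. GNL does so without Col-0 t0 replicate 1 (0.09) and hex t0 replicate 3 (0.05), with a range of -0.16 to 0.09.

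For the hex difference 43.3% of simulated 1.5-fold and 65.7% of 2-fold changes were recovered.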

Other observations

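The test in this part was chosen only after the result was seen. Of 22 iron acquisition genes, 18 fell and 0 rose in high light against low light in Col-0 by edgeR (median log2 fold change -1.67), 20 fell and 0 rose in hex (-1.45) and 22 fell and 0 rose in GNLox (-2.41). The ferritin gene FER1 rose (2.97 in Col-0, 2.65 in hex and 3.44 in GNLox). A lower share of root RNA may be the cause, since these genes are expressed in roots. Of 15 root markers without IRT1, 12 fell and 1 rose in Col-0 (median -0.69), 7 fell and 1 rose in hex (-0.51) and 11 fell and 0 rose in GNLox (-0.90). The iron genes lie below the root markers by -0.98 ± 0.66, -0.95 ± 0.59 and -1.51 ± 0.81 (bootstrap standard error), so the 2 explanations, less root RNA and an iron response, cannot be told apart, because each difference is under 2 standard errors.

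In GNLox t6LL replicate 3, GNC is read at 7.74 CPM, the highest value among the 3 libraries of that group.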
